A study of Mus musculus with 4 samples.

How the data were processed

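CUT&Tag libraries of NR1D1 from primary mouse aortic smooth muscle cells, 1 after 24 h with PBS and 1 after 24 h with vasostatin-2, were analysed as peak lists. The IgG libraries of both treatments were not analysed here. All libraries carry the same batch label, and nothing measures the spread between cultures.

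Reads were trimmed and aligned and peaks called upstream with Trimmomatic 0.39, BWA 0.7.17 and MACS2 2.2.7.1 on build mm10, per the submitters' processing notes, which name the tools without roles or settings. Each list comes from 1 library, with no replicates pooled. The files have no header, and their 10 columns follow the caller's standard order. The deposited fold enrichment is the ratio of the summit to the local background. The deposited -log10 p-value and -log10 q-value belong to the summit, and the smallest -log10 q was 1.32 in the PBS list and 1.31 in the vasostatin-2 list. The deposited score equals the -log10 q scaled by 10 and rounded down, and was not used further. Start, end and summit positions are the authors' coordinates on mm10, written here from 1. Fold, p and q are the authors' values and served to describe, rank or filter peaks within their own list.

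The number of fragments at each summit and its background were recovered from the deposited fold and -log10 p by solving the caller's Poisson formula for whole fragments. A solution within 0.0005 of the deposited -log10 p was found for 100% of peaks in both lists, and 4 PBS peaks had a next solution less than 10 times farther off. On 3000 simulated peaks the step returned 100% of the fragment numbers. The background had a floor of 0.31 fragments in the PBS library and 0.381 in the vasostatin-2 library. Above the floor it moved in fixed steps, read as 1 fragment spread over a window of 10000 bp, the caller's usual setting, which was assumed. Floor and step together gave a depth of the vasostatin-2 library of 1.32 relative to PBS; total fragments were not given in the sources used here. The summit's own fragments exceed the floor at 940 PBS peaks and 271 vasostatin-2 peaks (237 when they must exceed it by 1%), and the background was below their own contribution by more than 1% at 0 of them. Such a pattern arises when the background is taken from the NR1D1 library itself. Fold enrichment then falls where several strong peaks lie close together, and regions of repeated sequence are not removed by a control.

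Peaks were called shared when they overlapped the other list by at least 1 bp (bedtools 2.31.1; the overlap step gave the same result as bedtools for 100% of 4000 simulated peaks). Chance overlap came from 1000 random placements within each chromosome, from 3000000 bp to the last gene end or peak, whichever lay farther, with a one-sided permutation p. Genes came from the RefSeq table of GRCm38.p6, the assembly of mm10, with 49943 genes on chromosomes 1 to 19, X and Y. It gives the start and end of each gene but no strand, exons or sequence. For that reason the planned classes (promoter, untranslated region, exon, intron) were replaced by gene end (summit within 1 kb of either end), inside a gene, and intergenic. The planned motif search and the matching of random lists on promoter GC content were not run. Genes with a peak were protein-coding genes with a peak within 3 kb of either end. Any overlap of the peak with that window counted, and 1 peak could count for several genes.

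For 15 gene lists with 294 genes, all found in the table, the number with a peak was set against 10000 random lists matched on gene length in 10 classes, with a two-sided permutation p and Benjamini-Hochberg adjustment over the lists of a library. In simulations of this step 4.0% of 100 random lists and 90.0% of 100 lists planted with many extra hits passed an unadjusted 0.05. Power after adjustment, for shorter lists or for a weaker excess was not simulated. These p-values describe 1 library against other genes. Shares carry 95% Wilson intervals and counts of peaks exact Poisson intervals. Signal at shared peaks was compared in pairs of the same location class with at least 30 fragments together and under 100 in PBS, as the log2 ratio of summit fragments after division by 1.32, with bootstrap intervals.

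Gene lists, the shared-peak rule, windows, most alternatives and the rule for named genes were set before the data were examined. The rule named the 8 peaks of highest fold among shared, PBS-only and vasostatin-2-only peaks, by the nearest protein-coding gene end within 100000 bp and 1 peak per gene. It also named every core clock gene with a peak, up to 4 genes with the highest fold from every other list, and Nr1d1, Arntl, Chga, Acta2 and Myh11 in any case. A gene that this rule selects is not reported here. Chosen after seeing the data were the recovery of fragments, the settings built on it (at least 8 fragments, thinning of vasostatin-2 summits to the PBS depth, no peak of 100 or more), the paired signal, the exact test between clock and ubiquitous genes, and the gene families. Other alternatives were a reciprocal overlap of 50%, summits within 200 bp, a gap of up to 500 bp, the upper part of each list by fold, q under 1e-05, lists of equal length, other gene windows and ranking by width. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.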

Results

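NR1D1 (REV-ERB alpha), a nuclear receptor that represses transcription as part of the circadian clock, was mapped by CUT&Tag in primary smooth muscle cells from mouse aorta. In CUT&Tag an antibody tethers a transposase to chromatin, so that DNA beside the bound protein is cut out and sequenced. The cells were kept for 24 h with vasostatin-2, a peptide derived from chromogranin A, or with phosphate-buffered saline (PBS). The labels name 4 libraries, 1 with the NR1D1 antibody and 1 with control IgG for each treatment. The 2 NR1D1 libraries are compared here, and the IgG libraries were not analysed here. With 1 NR1D1 library per treatment no value has a replicate error, and no test was made of a treatment effect. Wilson and Poisson intervals cover counting error only, and bootstrap intervals the spread over peaks of these 2 libraries. The question behind the comparison was where NR1D1 sits in chromatin with and without vasostatin-2.

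Peaks rested on few fragments in both libraries. The median summit held 8 fragments in the PBS library and 7 in the vasostatin-2 library, and 56.3% and 66.1% of peaks had 4 to 8. The uniform background in the peak values put the vasostatin-2 library at 1.32 times the depth of the PBS library. The PBS list held 7377 peaks (95% Poisson interval 7210 to 7547) with a median width of 294 bp, covering 2564 kb. The vasostatin-2 list held 8816 peaks (8633 to 9002) with a median width of 255 bp, covering 2630 kb. Which list was longer depended on the rule: with at least 8 fragments they held 3906 and 3935 peaks, with q under 1e-05 2623 and 2320, and with at least 8 fragments after thinning of vasostatin-2 summits to the PBS depth 3906 and 2237.

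NR1D1 peaks of both libraries coincided at clock genes such as Per2, Nr1d1, Nr1d2, Dbp and Nfil3, but most peaks were found in 1 list. Of the PBS peaks 2628 (35.6%, 95% Wilson interval 34.5 to 36.7) overlapped a vasostatin-2 peak by at least 1 bp. Of the vasostatin-2 peaks 2649 (30.05%, 29.1 to 31.01) overlapped a PBS peak. Random placement of the vasostatin-2 peaks within their chromosomes gave a mean of 18.1 such overlaps, so the observed number was 147-fold higher (permutation p = 0.001, the smallest that 1000 placements give). When peaks at gene ends were placed at other gene ends, the mean was 61.1 and the excess 43.4-fold. Sharing rose with the number of fragments: 7.94% of PBS peaks with 4 to 5 fragments had a counterpart, against 92.0% (89.1 to 94.2) of those with 21 to 49. In the vasostatin-2 list the same classes gave 5.35% and 90.6% (85.9 to 93.8). Ranked by the authors' fold enrichment within each list, the top decile was shared at 82.1% in the PBS list and 66.3% in the vasostatin-2 list, and the bottom decile at 6.78% and 4.65%. A peak of few fragments that was missing from the other list is therefore not shown to be absent there.

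**Figure D1:**
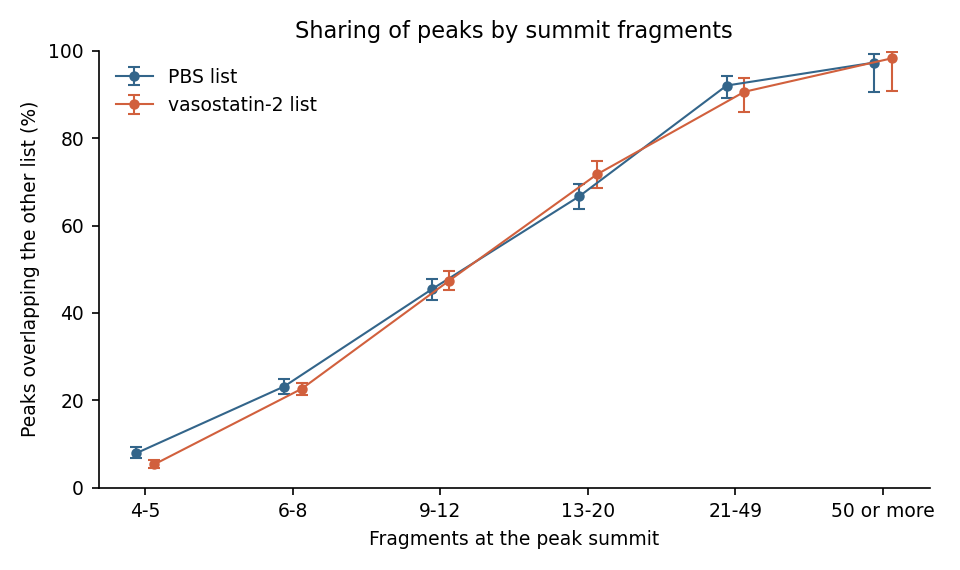
Share of peaks that overlap the other list (y axis, percent) by the number of fragments at the peak summit (x axis), for the PBS list (blue) and the vasostatin-2 list (orange). Points are shares and bars 95% Wilson intervals, which cover counting error only; both curves climb from under 10% at 4 to 5 fragments to over 90% at 21 or more.

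Peaks at the ends of genes made up a larger part of the PBS list than of the vasostatin-2 list. In the PBS list 2966 peaks (40.2%, 95% Wilson interval 39.1 to 41.3) had their summit within 1 kb of either end of an annotated gene. In the vasostatin-2 list 2206 peaks (25.02%, 24.1 to 25.9) did, although that list was longer. Randomly placed peaks lay there at 6.52% and 6.46%. Gene ends held 49.6% of the shared peaks as listed for PBS, 35.0% (33.7 to 36.4) of the PBS-only peaks and 14.6% (13.7 to 15.5) of the vasostatin-2-only peaks. Peaks inside genes but away from their ends made up 34.3% of the PBS list and 40.4% of the vasostatin-2 list, and intergenic peaks 25.5% and 34.6%. By fragments, 18.03% of PBS-only and 11.5% of vasostatin-2-only peaks were at gene ends with 4 to 5 fragments, 37.4% and 16.8% with 6 to 8, and 49.1% and 16.2% with 9 to 12. The gap was widest with 13 to 20 fragments, at 60.5% and 12.7%. With 21 to 49 the shares were 29.4% of 34 peaks and 5.0% of 20. These fragment classes were not scaled for depth. The gene table used here gives no strand, so starts and ends of genes were not told apart.

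**Figure D2:**
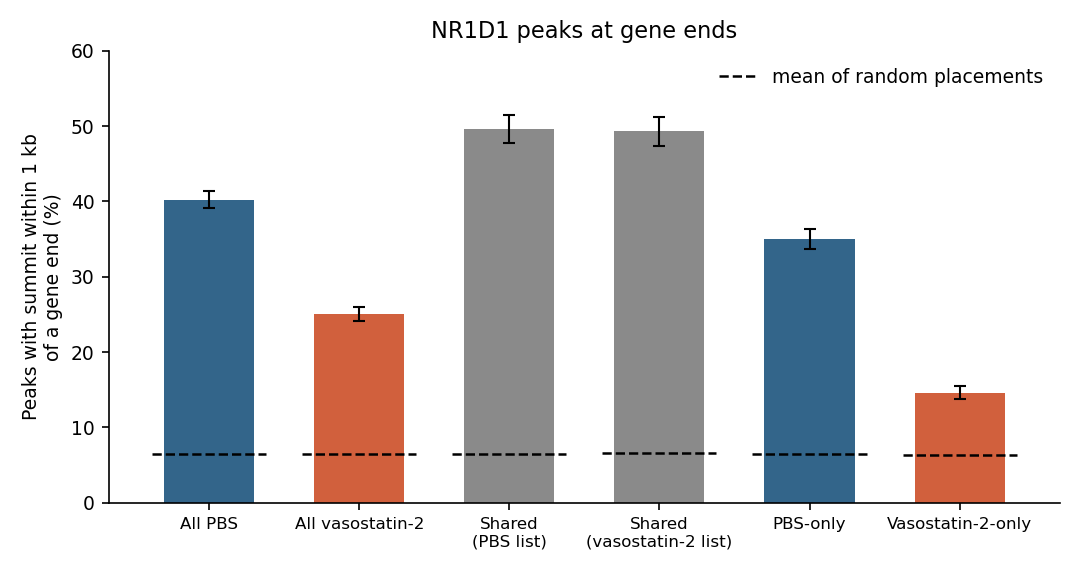
Percent of peaks with the summit within 1 kb of either end of a gene (y axis) in the whole lists, in shared peaks and in peaks of 1 list (x axis). Bars are shares, error bars 95% Wilson intervals (counting error only) and dashed lines the mean of random placements; the vasostatin-2-only peaks stand at 14.6% and the PBS-only peaks at 35.0%, both above the dashed lines.

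At shared sites the vasostatin-2 library held less depth-scaled signal, with the lowest median at gene ends. Of 388 pairs of shared gene-end peaks with at least 30 fragments together, 97.2% had fewer fragments per unit of depth in the vasostatin-2 library. The median log2 ratio of depth-scaled summit fragments (vasostatin-2 over PBS) was -1.05 (95% bootstrap interval -1.09 to -0.98). At 277 pairs away from gene ends the median was -0.56 (-0.68 to -0.46), and 75.8% were lower. At the 36 pairs with at least 100 fragments in PBS, few of them at gene ends, it was -0.38 (-0.70 to -0.24), and 97.2% were lower. These medians and shares rest on the inferred depth factor of 1.32, and the differences between the medians do not. At Per2, a core clock repressor, the summit held 63 fragments in the PBS library and 39 in the deeper vasostatin-2 library. At Relb, an NF-kB subunit, it held 56 and 33, and at Vcl, which encodes the adhesion protein vinculin, 24 and 10. These ratios compare the 2 libraries and not the treatments.

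The strongest peaks found in 1 list lay mostly inside genes or between them. Taking the highest fold, 1 peak per gene and a gene end within 100 kb, 3 of the 8 PBS-only peaks were at gene ends and 0 of the 8 vasostatin-2-only peaks. The PBS-only peak of highest fold (25.003-fold, 167 fragments) was inside Tmem267 on chromosome 13, 119598953 to 119599159. Others were near Gtpbp4, a GTPase of ribosome assembly (17.8-fold, 38 fragments), inside Abhd6, a monoacylglycerol lipase (15.3-fold), and at an end of Immt, which encodes a protein of mitochondrial cristae (12.5-fold, 399 bp away). Canx, which encodes the chaperone calnexin, had a PBS-only peak of 10.7-fold 111 bp from an end. Further PBS-only peaks were nearest to Gm40363, Msl2 and Abcb1a. The vasostatin-2-only peak of highest fold (19.1-fold, 44 fragments) was inside Pacs1 on chromosome 19, 5149004 to 5149201. Next by this rule came peaks inside Tcf4, a basic helix-loop-helix transcription factor (14.2-fold, 23 fragments), and Ror2, a receptor for Wnt5a (13.3-fold, 23 fragments). Others were inside Bank1 (12.8-fold) and Gphn (12.1-fold), which encodes the synaptic scaffold gephyrin, or nearest to Gm32936, Pdia4 and Cmas. The named PBS-only peaks were 201 to 854 bp wide (Tmem267 207 bp) and the vasostatin-2-only peaks 198 to 551 bp (Pacs1 198 bp). The background step gave fragment lengths of 196 and 183 bp. Median widths were 264 bp for PBS-only and 235 bp for vasostatin-2-only peaks, against 384 and 340 bp for shared peaks. Whether narrow stacks of fragments reflect NR1D1 was not tested. The shared peaks of highest fold by the same rule in the vasostatin-2 list, nearest to B230307C23Rik, Tmem196, Adgre5, Rpusd4, Atrnl1, Chl1, Vmn2r87 and Gm525, had 249 to 766 fragments and 34.7-fold to 42.4-fold enrichment, and none was at a gene end. These genes only mark the sites, at 7524 to 97525 bp. The peaks named by B230307C23Rik, Tmem196 and Vmn2r87 were the last of their chromosome and lay past its last annotated gene. No regions of repeated sequence were masked here, and whether these shared peaks reflect NR1D1 binding was not tested.

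Among protein-coding genes 1972 had a peak within 3 kb of either end in both lists, 1982 in the PBS list alone and 1058 in the vasostatin-2 list alone, of 21887 genes. Independent lists of these sizes would share 547 genes. With at least 8 fragments after thinning to the PBS depth the counts were 960, 1849 and 201 in the same order. Clock genes and ubiquitously expressed genes were the lists that passed the test. In the PBS list 12 of 24 core clock and clock output genes had such a peak, where random lists matched on gene length gave a mean of 4.74 (two-sided permutation test, adjusted p = 0.0165). In the vasostatin-2 list 10 of 24 did, against 3.62 (two-sided permutation test, adjusted p = 0.033). Ubiquitously expressed genes passed in the PBS list, with 10 of 18 against 3.60 (permutation test, adjusted p = 0.0165), and in the vasostatin-2 list 6 of 18 did against 2.70 (permutation test, adjusted p = 0.539). The share of clock genes with a peak, 50% (95% Wilson interval 31.4 to 68.6), did not differ detectably from the 55.6% (33.7 to 75.4) of ubiquitous genes in the PBS list (Fisher's exact test, two-sided p = 0.764). In the vasostatin-2 list the shares were 41.7% and 33.3%, again with no detectable difference (Fisher's exact test, two-sided p = 0.75). With a window of 1 kb neither list passed in the PBS library, with 10 clock genes and 8 ubiquitous genes (permutation test, adjusted p = 0.0585 for both).

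The clock genes with a peak in both lists were Per1, Per2, Cry2, Nr1d1, Nr1d2, Dbp, Nfil3, Bhlhe40 and Ciart. The Per2 peak lay inside the gene on chromosome 1, 91458054 to 91459016 in the PBS list, 921 bp from a gene end, with 13.9-fold enrichment in PBS and 11.1-fold in vasostatin-2. NR1D1's own gene had a peak on chromosome 11, 98774910 to 98775726, 30 bp from an end, with 34 fragments in PBS and 20 in vasostatin-2. Its paralog Nr1d2 had 22 and 15 fragments, and Nfil3, a transcriptional repressor of D-box genes, 28 and 23. Dbp, an activator at D-boxes, had 31 and 21, and Per1 37 and 35. Bhlhe40, a repressor induced by the clock, had 18 and 17, and Ciart 12 and 6. The Cry2 peaks were at different sites, with 18 fragments 2750 bp from an end in PBS and 12 fragments 197 bp from an end in vasostatin-2. Cry1 (9 fragments), Bhlhe41 (11) and Csnk1e (6) had a peak in the PBS list alone, and Timeless (7) in the vasostatin-2 list alone. Arntl, the BMAL1 gene and a known NR1D1 target, had no peak within 3 kb of either end of its 135656 bp span. It had 3 PBS peaks and 1 vasostatin-2 peak within the gene or 10 kb of it. Transcript starts inside the span were not given, so a peak at an Arntl promoter is not excluded.

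**Figure D3:**
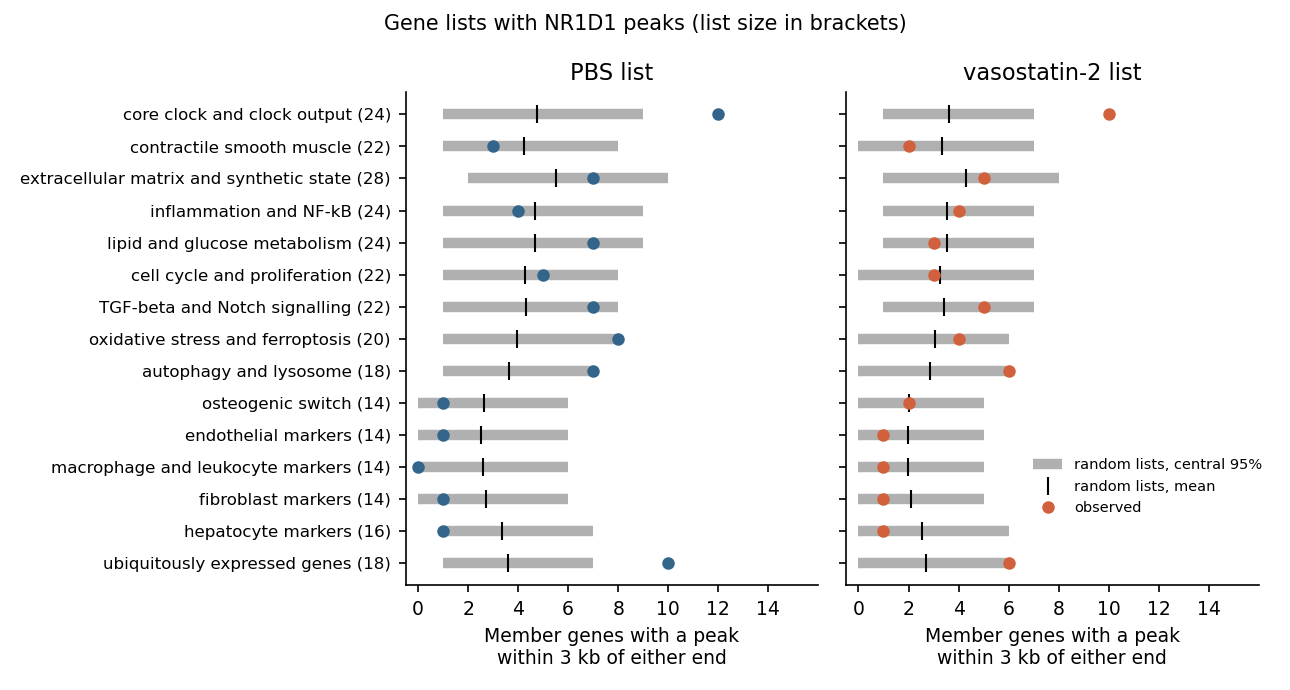
Number of member genes with a peak within 3 kb of either end (x axis) for 15 gene lists (y axis, list size in brackets) in the PBS list (left, blue) and the vasostatin-2 list (right, orange). Grey bars are the central 95% of 10000 random lists matched on gene length and ticks their mean; core clock genes lie outside the grey bar in both panels, with 12 and 10 of 24, and ubiquitously expressed genes in the PBS panel, with 10 of 18.

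The remaining 13 lists did not pass the test in either library. Contractile smooth muscle genes had a peak in 3 of 22 cases in the PBS list and 2 of 22 in the vasostatin-2 list. These were Vcl in both, Smtn and Srf in PBS and Cald1 in vasostatin-2. Acta2 and Myh11, the usual contractile markers, had no peak at an end, and neither did Chga, which encodes the precursor of vasostatin-2. Within the gene or 10 kb of it Myh11 had 1 peak in each list, and Acta2 and Chga had 0. Of 28 matrix and synthetic-state genes 7 and 5 had a peak, among them Fn1 (fibronectin) and Klf4, a factor of smooth muscle phenotype switching, with 10 and 11 fragments, and Mmp14 in PBS and Vcan in vasostatin-2. Inflammatory and NF-kB genes counted 4 of 24 in each list, with Relb and Rela in both, Rela at different sites, and Icam1 in PBS. Lipid and glucose genes counted 7 and 3 of 24, with the sterol regulators Srebf2 and Insig1 and the elongase gene Elovl3 in PBS and Fasn in both. Cell cycle genes counted 5 and 3 of 22. Cdk2 had 35 and 29 fragments, Cdk4 15 and 18, and Pcna (16 fragments) and Cdkn1a (13) a peak in PBS. The Cdk2 summits lay outside the gene, 1493 and 1636 bp from an end.

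TGF-beta and Notch genes counted 7 and 5 of 22, with Ski and Smad6, inhibitors of SMAD signalling, in both lists at 20 and 13, and 25 and 13 fragments, Ccn2 in both and Smad2 in PBS. Oxidative stress and ferroptosis genes counted 8 and 4 of 20 (permutation test, adjusted p = 0.29 and 1.0). Nfe2l2, the NRF2 gene, had 20 and 9 fragments, its target Nqo1 14 and 9, Sod2 11 in PBS and Tfrc 10 in vasostatin-2. Autophagy and lysosome genes counted 7 and 6 of 18. Wipi1 had 25 and 22 fragments and Gabarap 18 and 10, Rb1cc1 had 10 in PBS, and Ulk1, the kinase that starts autophagy, a vasostatin-2 peak of 11.03-fold with 20 fragments. Osteogenic genes counted 1 and 2 of 14 (Slc20a1 in both, Tnfrsf11b in vasostatin-2). Markers of other cell types were not told apart from random lists: endothelial genes counted 1 and 1 of 14 (Nos3; random means 2.52 and 1.98) and macrophage and leukocyte genes 0 and 1 of 14 (Cd68; 2.59 and 1.98). Fibroblast genes counted 1 and 1 of 14 (Pdpn, then Mfap5; 2.71 and 2.08) and hepatocyte genes 1 and 1 of 16 (Hpx, then Apoa2; 3.34 and 2.54). Of the ubiquitous genes Tubb5 had 24 and 17 fragments, Eef1a1 17 and 12, and Rpl13a 13 and 18. The Tubb5 summits lay outside the gene, 3115 and 3149 bp from an end, so only the edge of the peak reached the window.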

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

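Settings based on fragments, the equal lists for location and the leaving out of very high peaks were chosen after seeing the data; the others were planned. In every setting in which it was recomputed the share at gene ends was higher in the PBS list than in the vasostatin-2 list, and higher in PBS-only than in vasostatin-2-only peaks. Of the recomputed main values 58 moved outside the interval of the reported share or beyond 1.5 times the reported count, and 36 stayed inside. Of the single lists of genes 88 results kept their side of the threshold and 2 lost it, clock and ubiquitous genes in PBS with a 1 kb window (2.56 and 2.74 times the random mean, permutation test, adjusted p = 0.0585 for both, against 0.006 to 0.0195 in their other settings). Under the stricter settings, gene-end shares of PBS-only and vasostatin-2-only peaks refer to peaks with no overlap in the other full list, so their totals differ from the counts of peaks in 1 list, which compare the reduced lists. Peak counts and shares follow the strictness of a rule by its construction; beyond that the cause was not tested. Most peaks have 4 to 8 fragments, which limits every count of peaks in 1 list.

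Reciprocal overlap lowered the shared part to 26.5% of PBS and 22.2% of vasostatin-2 peaks, and summits within 200 bp to 29.6% and 24.8%. A gap of 500 bp raised it to 37.5% and 31.6%. With q under 1e-05 it was 38.7% and 43.8%, the order of the lists turned round. With lists of equal length it was 33.5% and 33.7%, and 26.1% of vasostatin-2 peaks were at gene ends. In the upper part of each list by fold 42.6% and 35.8% were shared, leaving 2117 PBS-only and 2832 vasostatin-2-only peaks. Gene ends then held 48.5% of PBS, 28.1% of vasostatin-2, 42.8% of PBS-only and 12.7% of vasostatin-2-only peaks, and 1171 genes had a peak in both lists, 1306 in PBS alone and 543 in vasostatin-2 alone.

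With at least 8 fragments 45.2% and 45.3% were shared, with 2139 and 2154 peaks in 1 list, and gene ends held 52.2% of PBS, 32.6% of vasostatin-2, 49.5% of PBS-only and 15.9% of vasostatin-2-only peaks. After thinning to the PBS depth 32.6% and 57.5% were shared, with 2632 PBS-only and 951 vasostatin-2-only peaks. Gene ends then held 52.2%, 35.7%, 49.5% and 15.7% in the same order, and 960 genes had a peak in both lists and 201 in vasostatin-2 alone.

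Keeping gene-end peaks at gene ends lowered the excess of overlaps over chance to 43.4-fold. Within 3 kb gene ends held 51.1% of PBS, 36.5% of vasostatin-2, 46.3% of PBS-only and 26.5% of vasostatin-2-only peaks, and with protein-coding genes alone 35.9%, 21.03%, 30.95% and 10.9%. Any overlap with the window gave 41.6%, 26.2% and, for vasostatin-2-only peaks, 15.6%. With a 1 kb window 701 genes had a peak in vasostatin-2 alone and 0 gene lists passed in PBS. With gene bodies and 10 kb 3840 genes had a peak in both lists and 2297 in vasostatin-2 alone. Ranked by width, the top decile was shared more than the bottom decile by 61.7 percentage points in PBS and 65.0 in vasostatin-2. Leaving out peaks over 5 kb removed none. The alternatives for motifs and for GC content were not run. No paired analysis was possible because each group has 1 library.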

Other observations

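The tests at clock genes, the test of depth at gene ends and the Poisson test of strong peaks were chosen after their results or parts of them were seen; the other tests were fixed before their results were computed. Genes with a peak within 1 kb of an end were counted in families grouped by symbol or type after the lists were seen, and differences between families were not tested. All protein-coding genes counted 3233 and 2274 of 21887 (14.8% and 10.4%), where randomly placed peaks reach 299 and 347 genes on average. Ribosomal protein genes had one at 24 of 84 genes in PBS (28.6%, 95% Wilson interval 20.02 to 39.0) and 12 of 84 in vasostatin-2 (14.3%, 8.37 to 23.3, which includes the share of all protein-coding genes), with random means of 1.18 and 1.35. Mitochondrial ribosomal protein genes had one at 22 and 12 of 78. Histone genes had one at 16 of 67 in PBS and 2 of 67 in vasostatin-2, but neighbouring histone genes share peaks, and these rest on 8 distinct peaks and 1. Zinc finger genes of the Zfp series counted 63 and 49 of 397. Olfactory receptor genes, mostly silent outside the nose, had 3 and 2 of 1110, below the random means of 13.9 and 15.3. Pseudogenes had 68 and 65 of 9944, below the random means of 95.4 and 108.

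A small number of sites held very many fragments in both libraries. Whether these sites reflect NR1D1 binding was not tested. Peaks of at least 100 fragments numbered 38 in PBS and 36 in vasostatin-2, and 36 and 35 of them were shared. In the PBS and vasostatin-2 lists 25 and 23 of them were intergenic and 2 in each lay at gene ends. In each list 7 of them were the last peak of a chromosome and lay past its last annotated gene, and 13 and 12 lay between 3000000 bp and 200000 bp farther on. The highest were on chromosome 17, 13552176 to 13553138 (2125 fragments in PBS and 2371 in vasostatin-2), and on chromosome 2, 98666266 to 98667313 (2044 and 2065). After scaling for depth 35 of 36 pairs of such sites were lower in vasostatin-2. Without scaling some held more fragments in vasostatin-2, as at both sites above, and others fewer. The share of lower pairs therefore rests on the inferred depth factor of 1.32. Of the unshared ones, the PBS peak inside Tmem267 with 167 fragments had no vasostatin-2 peak within 2.73 kb. The vasostatin-2 peak inside Pacs1, with only 44 fragments, had no PBS peak within 30.6 kb. The other unshared peaks of at least 100 fragments were on chromosome 10 in PBS (111 fragments) and chromosome 2 in vasostatin-2 (305 fragments, 2.54-fold).

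Fewer gene-end peaks in the vasostatin-2 list ran against its greater depth. Without any thinning the deeper vasostatin-2 library had 1282 gene-end peaks with at least 8 fragments, against 2037 in PBS, the reverse of what depth would give. A loss of signal equal at all shared peaks is argued against by the log2 ratios. They were lower at gene ends than at other shared peaks by a gap of -0.49 (95% bootstrap interval -0.58 to -0.34). A poorer vasostatin-2 library stays open, since other shared peaks may include sites that do not depend on the antibody. These were not told apart, and the IgG libraries were not analysed here. A loss at gene ends whatever the gene stays open: at 6 pairs of clock gene peaks the median log2 ratio was -0.96, within the -1.40 to -0.60 of random sets of other gene-end pairs. With 1 library per treatment, a weaker reaction at open chromatin and an effect of vasostatin-2 on NR1D1 binding may both give this pattern, and no test here separates them.

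Vasostatin-2-only peaks lay mostly away from gene ends. Evenly placed random positions put 5.81% to 7.02% of them at gene ends in the central 95% of placements, and 14.6% were there. Such positions are therefore not the whole of this set, though they may be part of it. Background that itself favours gene ends was not tested, since the IgG libraries were not analysed here. Depth may account for the number away from gene ends: with at least 8 fragments 696 remained after thinning, against 898 PBS-only peaks, and 1598 without thinning. An effect of the treatment on these sites stays open.

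Most peaks were in 1 list, and sampling of few fragments is a candidate explanation for the weak ones. Of 940 PBS peaks with at least 16 fragments 16.1% (95% Wilson interval 13.9 to 18.5) were missing from the vasostatin-2 list. Poisson sampling of independent fragments at equal occupancy would lose 0.345%, so under those assumptions sampling does not cover the strong ones. The peaks were picked by their own PBS count, which may overstate their occupancy. With 21 to 49 fragments 34 of 427 PBS peaks were missing, and with 50 or more 2 of 74. The missing part was 15.01% at gene ends, 20% inside genes and 14.2% between genes. In the other direction 4.69%, 19.3% and 22.5% of vasostatin-2 peaks with at least 16 fragments were missing from the PBS list. That cut was not scaled for the greater depth of the vasostatin-2 library, so the directions are not on an equal footing. Shared peaks had less depth-scaled signal in vasostatin-2, so sampling at a lower occupancy is not excluded. Whether fragments at a summit were independent was not examined. Differences between the cultures and the treatment itself stay open, since each has 1 library.

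It was asked whether peaks at clock genes also exceed other gene-end peaks in fold. In the PBS list the median fold of 12 clock genes, 7.13, stood at percentile 96.5 of random sets of genes with a peak, inside the central 95% of 4.91 to 7.24. In the vasostatin-2 list the median of 10 clock genes, 6.65, stood at percentile 98.3, above 6.52. Ubiquitous genes stood at percentile 21.1 in PBS (median 5.36, 10 genes) and 97.2 in vasostatin-2 (median 6.92, 6 genes). The hypothesis thus held in 1 of the 2 lists. In that list ubiquitous genes had the higher median, so the result does not set clock genes apart. The difference between clock and ubiquitous genes was not tested.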
